A study of Trichodesmium erythraeum IMS101 and Trichodesmium erythraeum 21-75 with 11 samples.

How the data were processed

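The series holds whole-genome bisulfite sequencing of 11 Trichodesmium DNA samples. Per the labels, about 100 ng of DNA was bisulfite treated, made into libraries with a kit for low input and sequenced on a NextSeq, and the 3 libraries of each CO2 group are biological replicates. For the 6 IMS101 libraries the deposited table gives, per cytosine of the chromosome and strand, the counts of reads covering it and the counts of reads called methylated. Both are raw counts, since methylated reads never exceeded coverage in any of the 2646147 cytosines, and cytosines without coverage are listed too. For each of the 5 single libraries the deposited list gives the methylation level as a fraction and the coverage as counts of reads, and holds only cytosines with a level of at least 0.2 and coverage of at least 5, the lowest values in each file. The aligner, the methylation caller and the filters on reads are not given in the sources used here.

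Positions in the files start from 0: with 1 added, 2418 protein-coding genes showed start and stop codon patterns on the forward and 2382 on the reverse strand, out of 4989. Genes and positions follow the RefSeq annotation of the IMS101 chromosome, with 5449 genes, of which 743 have a symbol. No genome sequence was used. The letters C and G around each cytosine were read from the listed cytosines of both strands, and all other bases are written W (A or T), so a fixed motif such as CGATCG was searched as CGWWCG. Gene lists were matched by symbol or biotype, and 14 of 21 fixed lists had members; carbon fixation, retroelements, restriction and DNA methylation, regulators, toxin-antitoxin, calcium-binding repeats and WD40/TPR proteins had none by symbol. A further 11 lists were taken from the symbols after the files were opened and adjusted separately. The library 21-75 is on another sequence than the IMS101 chromosome, so it was left out of all comparisons by position and of the lists of gene overlaps.

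A cytosine counted as methylated at 380 µatm when it had at least 10 reads in each of the 3 libraries and a mean level of at least 50%. Contexts, motifs, gene classes and lists were compared by two-sided Fisher's exact tests against the other covered cytosines, with Benjamini-Hochberg adjustment over lists, features or words, and binomial intervals are exact Clopper-Pearson at 95%. The sequence words GCSGC, CGWWCG, CWGCWG, WCGW and CWCCWW were defined after the data were seen. The groups at 380 and 750 µatm were compared with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test on methylated and unmethylated reads with an intercept per library, at sites with at least 10 reads in all 6 libraries and a mean level of at least 10%, and on reads summed per gene. Calls are at an adjusted p under 0.05; 3399 sites and 855 genes were below an unadjusted 0.05, and limma 3.58.1 on log2 odds with 1 added to each count called 1626 sites and 373 genes. Mean levels of libraries were compared by exact permutation tests. The single libraries were compared by position and strand, without replicates. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

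The depth per cytosine averaged 83.4 to 209 reads in the IMS101 libraries, and 96.5 to 97.3% of cytosines had at least 10 reads in each. Reads methylated outside the words, an upper bound for the mean share of unconverted bases there, were 0.373%, 0.382% and 0.345% at 380 µatm and 0.337%, 0.338% and 0.639% at 750 µatm. The tests were run on simulated data with known changes, where each site was drawn on its own with 1 spread, estimated within groups, for all 6 libraries. For sites, 1 of 100 changes of 10 points and 40 of 100 of 20 points were recovered with 0 false of 41 calls. For genes, with every tested site of a changed gene lowered, these were 83 and 98 of 100 with 5 false of 186 calls. In the data, changes on the 2 strands of WCGW pairs went together (r = 0.886 across pairs). Replicate 3 at 750 µatm also stood apart, as given below. Neither was simulated, so error rates in the data may be higher. Libraries of 1 group differed beyond sampling of reads, with a chi-square per site of 1.05 (p = 5e-06) for the closest pair, 380 µatm replicates 1 and 2. Pairs within 380 µatm reached 1.25, and replicates 1 and 2 at 750 µatm stood at 1.10 from each other. Replicate 3 at 750 µatm stood at 2.29 and 2.02 from those 2 (r = 0.970 and 0.974 across sites) and at 2.30, 2.43 and 3.19 from replicates 1, 2 and 3 at 380 µatm (r = 0.975, 0.975 and 0.967), so it was about as far from part of the other group as from its own.

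Genes and sites were named by a rule set before the data were examined. For the IMS101 methylome it takes the 15 genes with the most methylated cytosines and up to 4 genes of each fixed list; for 750 against 380 µatm, up to 10 sites and 10 genes in each direction with the smallest adjusted p; for all methylomes, the 15 genes with the most common cytosines and up to 2 genes of each list. Called members of lists are named as well. Alternatives covered the coverage minimum, the level minimum, limma, pooled Fisher tests, replicate blocks, leaving out each library in turn and stricter lists; reads thinned to the shallowest library, WCGW alone or left out, and gene lists on 1 strand alone were added after the data were seen. The last counts each place once, since the 4 words read the same on both strands, and of their places with any methylation 87.8 to 100% had it on both. Overlaps within each word were also added then.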

Results

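Cytosine methylation was measured by whole-genome bisulfite sequencing in Trichodesmium, a filamentous marine cyanobacterium that fixes nitrogen. Bisulfite turns unmethylated cytosine into a base read as thymine, so the share of reads that still show cytosine is the methylation level of that position. Strain IMS101 of Trichodesmium erythraeum was grown at 380 µatm CO2 (3 libraries) or moved from 380 to 750 µatm and sampled after 2 weeks, about 5 generations (3 libraries). A further 5 single libraries without replicates came from the isolates IMSB and 21-75 (T. erythraeum) and VI-1 (T. thiebautii) and from handpicked natural populations of the western South Atlantic, named St-06 and St-08. Mean coverage per cytosine of the IMS101 chromosome was 182, 209 and 193 reads in the 380 µatm libraries, and 183, 179 and 83.4 reads in the 750 µatm libraries, with replicate 3 at 750 µatm the shallowest. Median coverage of the cytosines listed for the single libraries was 166 reads in IMSB, 44 in 21-75, 6 in VI-1, 8 in St-06 and 8 in St-08. Values below are means ± SD over n = 3 libraries unless stated, and S and W stand for C or G and for A or T.

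The first question was which cytosines of IMS101 carried methylation at 380 µatm. Methylation sat at a small set of short sequence words, and most of it was in CpG. Of 2568448 cytosines covered by at least 10 reads in each of the 3 libraries, 12427 (0.484%) had a mean level of at least 50%, with 12255, 12379 and 12730 in the libraries taken alone. Their mean level was 83.7%, 84.0% and 84.9% in the 3 libraries, against 0.432%, 0.440% and 0.409% at the other covered cytosines. CpG held 8616 of them (69.3%, exact 95% binomial confidence interval 68.5 to 70.1%), C followed by A or T and then G held 1943 (15.6%), and CCG held 1868. None of 1879551 covered cytosines in the remaining context, CHH, reached 50%, which allows a share of up to 0.0297% of the methylated set by the same interval. The odds of methylation were 21.4 times higher in CpG and 8.35 times higher in CCG than in all other contexts (Fisher's exact tests, with p too small for the software to represent). For C, A or T, then G they were 1.06 times higher. All intervals cover counting error alone, and cytosines are not independent replicates.

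The methylated cytosines fell into 4 words, which were defined after the data were seen. The second base of GCSGC was methylated at 3731 of 3733 places with a mean level of 93.8% ± 0.0738 (SD, n = 3), and the fourth base of CWGCWG at 1943 of 12656 places (15.4%) with a level of 95.3% ± 0.0298 (SD, n = 3). The first base of CGWWCG, which includes the fixed motif CGATCG, was methylated at 3351 of 7842 places (42.7%) with a level of 72.2% ± 1.56 (SD, n = 3). Where CGWWCG was flanked as GCGWWCGC, 3020 of 5773 places were methylated, against 331 of 2069 places with other flanks. The cytosine of WCGW was methylated at 3324 of 79185 places (4.20%) with a level of 79.6% ± 0.920 (SD, n = 3), and 78 methylated cytosines lay outside these words. Both strands were methylated in 99.9% of GCSGC pairs, 100% of CWGCWG pairs, 91.8% of CGWWCG pairs and 87.8% of WCGW pairs in which at least 1 strand was. Levels between 10 and 90% were found at 71.5% of CGWWCG places, and 4376 of the 5472 WCGW cytosines at 10% or more lay in that range. Of the 12656 CWGCWG places, 13 did, and 1932 were at 90% or more. Since W leaves A and T open, a share of places methylated can pool sequences that are methylated to different degrees, which could not be told apart. The fixed motifs CCGG and CCWGG had no methylated cytosine at either of their cytosines (0 of 11570 and 0 of 15884 at the second base). The third base of CYCGRG had 369 of 4787 (7.71%), 355 of them in CWCGWG. Here Y was searched as C, A or T and R as G, A or T, so that words such as CACGTG count too. GATC, searched as GWWC, had 73 of 136959 (0.0533%). GCGC had none at its inner cytosine (0 of 8692) and the inner base of GGCC had 239 of 12113 (1.97%). All 239 lay in GGCCGC, where this base is the second base of GCSGC and 239 of 239 places were methylated.

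**Figure D1:**
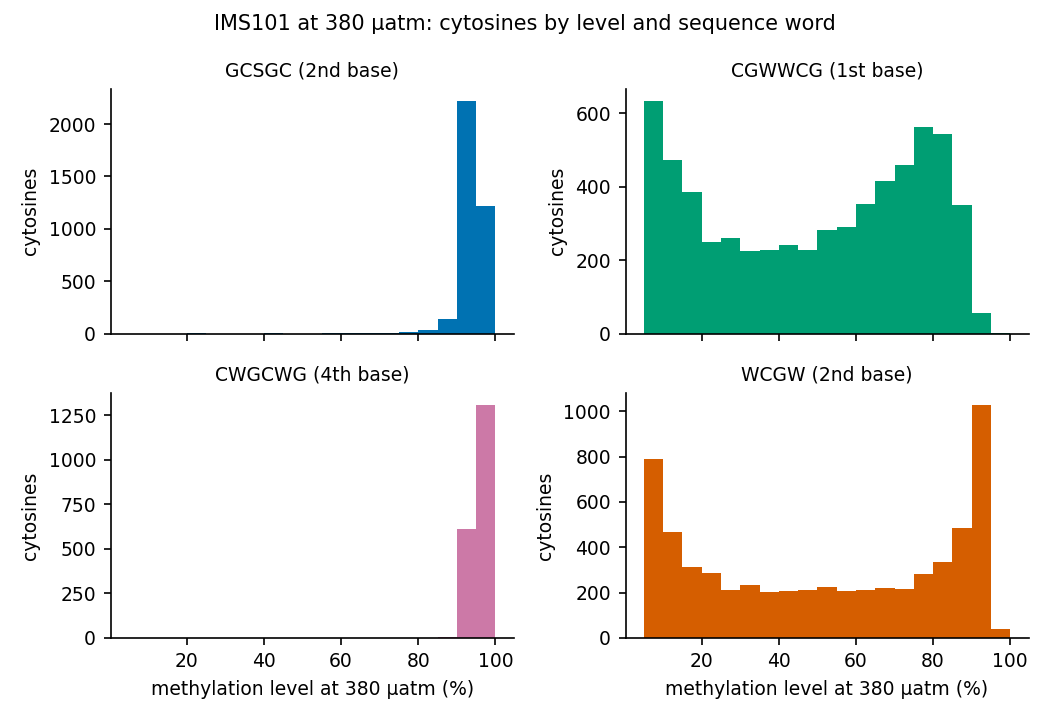
Number of cytosines (vertical axes, each with its own scale) by mean methylation level over the 3 libraries at 380 µatm (horizontal axes, %, cytosines at 5% or more, bins of 5 points), for the 4 sequence words. GCSGC and CWGCWG cytosines gather near 93.8% and 95.3%, while CGWWCG and WCGW cytosines spread over the whole range.

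Methylated cytosines were denser in genes than between them. Protein-coding genes held 9633 of the 12427, 0.572% of their covered cytosines (odds ratio 1.81, Fisher's exact test, adjusted p = 3.5e-185), and the space between genes held 2378, or 0.295% (odds ratio 0.515, adjusted p = 5.7e-209). RNA genes had the highest density, 29 of 2480 cytosines or 1.17% (odds ratio 2.44, adjusted p = 3.2e-05, and 0.00187 and 0.0037 on the plus and the minus strand alone), and pseudogenes were close to the genome at large (0.518%, odds ratio 1.07, adjusted p = 0.172). Within 150 bases upstream of a start codon the density was 0.268% (odds ratio 0.533, adjusted p = 3.7e-56). The words followed this pattern to different degrees. GCSGC cytosines made up 0.179% of covered cytosines in protein-coding genes and 0.0741% between genes and were methylated nearly everywhere, whereas CGWWCG places were methylated more often between genes (53.3%) than in protein-coding genes (39.5%), and WCGW places less often (2.67% against 4.65%).

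At least 1 methylated cytosine lay in 2615 of the 5449 annotated genes (48.0%). The gene with the most was Tery_4958 (TERY_RS26055, positions 7553468 to 7558333 of the IMS101 chromosome) with 46, of which 38 were in GCSGC. It was followed by Tery_1546 (TERY_RS07150, 2353916 to 2359255) with 43, Tery_0826 (TERY_RS03905, 1308378 to 1312364) with 38, and Tery_4959 (TERY_RS26060, 7559014 to 7563648) and Tery_4754 (TERY_RS22955, 7290402 to 7300685) with 36 each. The other 10 of the first 15 (Tery_3830, Tery_3487, Tery_3266, Tery_3677, Tery_3459, Tery_0387, Tery_1841, Tery_1587, Tery_1975 and Tery_4362) held 32 to 22. In Tery_4362 (TERY_RS25810, 6723030 to 6725207), 20 of the 22 were in WCGW, unlike in Tery_4958, where 4 were.

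Of the 14 fixed gene lists with members, 2 differed in density from the other genes after adjustment over the lists. The tRNA genes also did when each place was counted once, on the plus or the minus strand alone (adjusted p = 0.00237 and 0.00698). The tRNA genes had 27 methylated among 1516 covered cytosines (1.78% against 0.569%, odds ratio 3.17, Fisher's exact test, adjusted p = 5.6e-06), located in 10 of 38 genes, with 6 in TERY_RS20035, 4 in TERY_RS17430, 3 in TERY_RS19960 and 2 in TERY_RS19700. The photosystem I genes had 4 of 2348 (0.170% against 0.571%, odds ratio 0.297, adjusted p = 0.0389), all in psaB, which encodes a core protein that binds the reaction centre chlorophylls. These are 2 places read on both strands, and on the plus or the minus strand alone the list did not pass (adjusted p = 0.549 and 0.370). None was found in the other 6 photosystem I genes, psaA among them. Nitrogen fixation genes had 10 of 3401 (0.294%, adjusted p = 0.118), with 2 each in nifB, nifD, nifS, nifU and nifK. The other 11 lists had adjusted p values from 0.118 to 1. The densest of them was the transposases, 4 of 211 cytosines in tnpA (1.90%, adjusted p = 0.118), and the sparsest the gas vesicle genes, 2 of 1007 in gvpN (0.199%, adjusted p = 0.328). Photosystem II had 20 (0.402%, adjusted p = 0.328), with 6 in psbD and 4 in psbC, which encode core proteins, and 2 each in psbQ and psbV2. Phosphorus acquisition had 35 (0.698%, adjusted p = 0.388), with 12 in the phosphate-binding protein gene pstS (Tery_3534), 8 of them in CWGCWG. Other genes with many were gyrB (14), a DNA gyrase subunit, the chaperone gene dnaK (Tery_1306, 10), uvrB (8) and mutS (8) of DNA repair, ndhI (6), atpC (6), atpA (5), rplT (4), rplD (4), feoB (4), a ferrous iron transporter, and 2 apcB genes (2 each) for the phycobilisome core. DNA replication and repair (0.643%), ribosomal proteins (0.522%), ATP synthase (0.642%), respiration (0.625%), phycobilisome (0.669%), iron (0.656%) and rRNA genes (0.419%, 2 in rrf) had adjusted p values from 0.388 to 1.

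Among 11 lists chosen from the gene symbols after the files were opened and before values per gene were seen, the group II intron proteins (ltrA) had 1 methylated of 5677 cytosines (0.0176% against 0.572%, Fisher's exact test, adjusted p = 7e-12). The cell wall and division genes had 70 (0.799% against 0.569%, adjusted p = 0.0369), 11 of them in murJ and 10 in mrdA. On the plus or the minus strand alone, ltrA still passed (adjusted p = 4.1e-05 and 1.6e-06) and the cell wall and division genes did not (0.284 and 0.231). The 9 others had adjusted p values from 0.0987 to 1: aminoacyl-tRNA synthetases 0.707%, central carbon enzymes 0.688%, nucleotide synthesis 0.690%, chaperones and Clp proteases 0.641%, nitrogen assimilation 0.568%, chlorophyll and heme synthesis 0.559%, cobalamin synthesis 0.555%, hormogonium polysaccharide genes 0.548%, and cytochrome b6f and plastocyanin 0.308%. Matched by symbol, the list of aminoacyl-tRNA synthetases also held hisG and proX genes, which do not encode synthetases.

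The second question was whether methylation differed after growth at 750 µatm. It was lower at many cytosines, and nearly all of these were WCGW cytosines or CpGs outside the 4 words. Of 18410 cytosines tested (10 reads in all 6 libraries and a mean level of at least 10%), 2343 were lower and 24 higher at 750 µatm (edgeR, adjusted p under 0.05). WCGW held 1977 of the lower calls, 39.3% of its 5026 tested cytosines (odds ratio 23.1 against all others), with a median change of -17.1 points among them. CpGs outside the words fell from 35.6% ± 1.70 to 18.9% ± 3.34 (SD, n = 3) over 328 tested cytosines, 326 of which had A or T on 1 side alone, and 292 of them were called lower. GCSGC had 6 lower and 4 higher calls among 3656 tested, CWGCWG 3 and 3 among 1929, and CGWWCG 53 and 0 among 5548.

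Mean levels per word show the same contrast, and 3 against 3 libraries cannot give an exact p below 0.1. Over WCGW cytosines at 10% or more, the level was 61.9% ± 1.32 at 380 and 53.5% ± 0.676 at 750 µatm (SD, n = 3), a difference of -8.45 points with all 750 µatm libraries below all 380 µatm libraries (exact permutation test, p = 0.1). The difference was -14.5 points for those between 10 and 50% and -4.10 points for those above. GCSGC differed by -0.370 points (93.8% ± 0.0671 and 93.5% ± 0.0856, SD, n = 3, exact permutation p = 0.1) and CWGCWG by -0.0328 points (95.3% ± 0.0293 and 95.3% ± 0.415, SD, n = 3, exact permutation p = 1). For CGWWCG the levels were 54.2% ± 1.62 and 50.6% ± 4.52 (SD, n = 3, exact permutation p = 0.3), and the spread came from replicate 3 at 750 µatm, at 45.6% against 51.9 to 55.9% in the other 5 libraries. Over all 11702 cytosines at 50% or more, the mean level was 85.5% ± 0.572 at 380 and 83.3% ± 1.26 at 750 µatm (SD, n = 3), a difference of -2.19 points in a two-sided exact permutation test with p = 0.1.

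**Figure D2:**
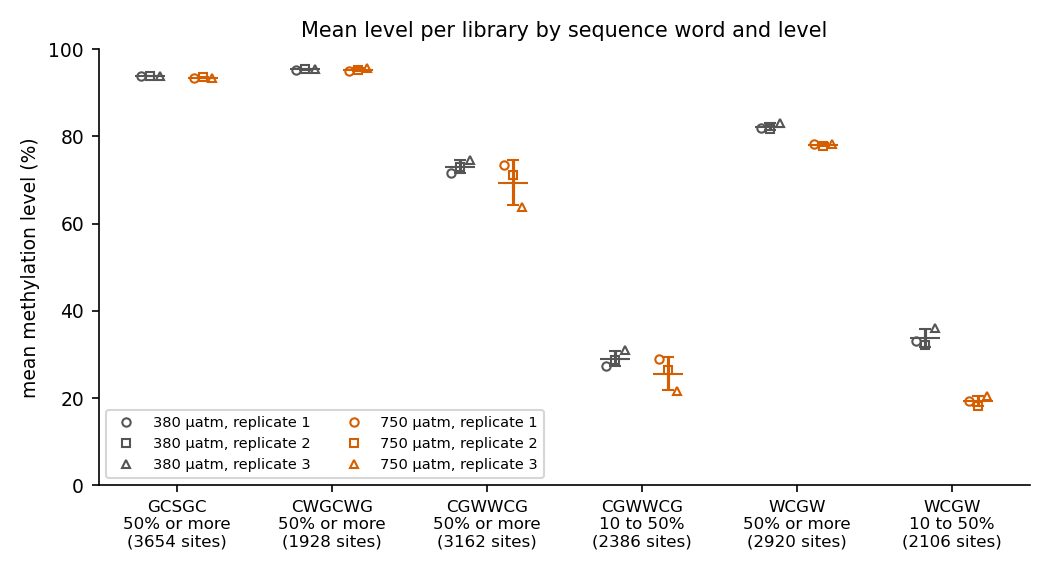
Mean methylation level (vertical axis, %) of each IMS101 library by sequence word and by mean level over the 6 libraries (horizontal axis, with the number of cytosines). Symbols are replicates, horizontal bars are means and error bars are SD over 3 libraries; the 750 µatm libraries lie below the 380 µatm libraries for WCGW, most clearly between 10 and 50%, where the means are 33.8% and 19.3%.

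The loss at WCGW was largest at intermediate levels. Cytosines at 40 to 60% at 380 µatm went from 50.1% ± 2.33 to 33.2% ± 2.13 (SD, n = 3), with 580 of 850 called lower, and those at 20 to 40% from 29.3% ± 2.24 to 15.7% ± 0.486 (SD, n = 3), with 663 of 929 called. At 90% or more, 11 of 1067 were called and the mean difference was -1.06 points. Calls also differed by flanking bases, and so did starting levels. Of GWCGWW and WWCGWC cytosines, at 39.5% and 39.3% at 380 µatm, 125 of 135 and 135 of 148 were lower, against 328 of 1183 for CWCGWW and 331 of 1149 for WWCGWG, at 69.2% and 68.2%. Among cytosines at 40 to 60% at 380 µatm, 278 of 303 with the flanks CWCGWC, GWCGWG, GWCGWW or WWCGWC were lower and 302 of 547 with other flanks. At 60 to 80% these were 173 of 224 and 217 of 707. The 4 flanks were grouped after their calls were seen. Both strands were lower at 806 of 2375 WCGW pairs tested on both, and 196 were lower on 1 strand. WCGW cytosines were called lower more often in protein-coding genes (42.1%) than between genes (29.9%, Fisher's exact test against all other WCGW cytosines, p = 1.2e-09, with the 2 strands counted separately) or in RNA genes (2 of 27).

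**Figure D3:**
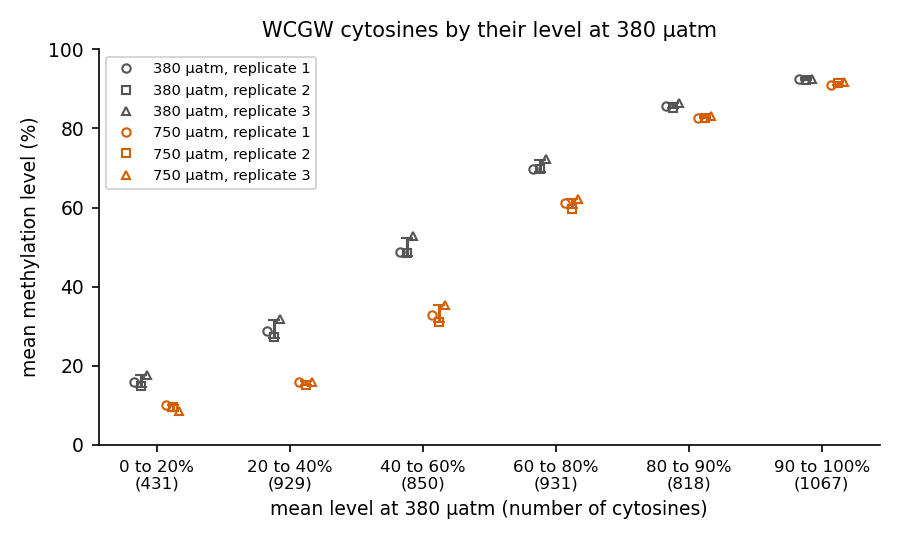
Mean level (vertical axis, %) of WCGW cytosines in each of the 6 IMS101 libraries, by their mean level at 380 µatm (horizontal axis, number of cytosines in brackets). Symbols are replicates and error bars are SD over 3 libraries; the gap between 380 and 750 µatm is widest from 20 to 60% and narrow above 80%.

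The 10 lower sites with the smallest adjusted p were all in WCGW and passed in all 6 tests that left out 1 library. The first lay in Tery_0826 at position 1312058 on the plus strand, at 41.2% ± 2.70 and 7.47% ± 6.33 (SD, n = 3, coverage 102 to 320 reads, edgeR adjusted p = 1.5e-10). The next was 141 bases from Tery_1759, at position 2679556 on the minus strand (54.5% ± 2.60 to 13.1% ± 9.34, SD, n = 3, coverage 59 to 189 reads). Further sites lay in Tery_2262 (3519590), Tery_4574 (7038706), Tery_1093 (1716494) and Tery_0380 (590878), and between genes near Tery_2061 (3216833), TERY_RS36810 (3765264), Tery_0386 (599895) and hpsB (6354392), a gene of the hormogonium polysaccharide group. Their differences ranged from -20.8 to -41.5 points.

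Of the 24 higher sites, 9 were in WCGW, 8 in the word CWCCWW, 4 in GCSGC and 3 in CWGCWG. The 2 strands of a CpG in dnaJ (Tery_1751, 2669092 to 2670216), a co-chaperone of dnaK, rose from 53.0% ± 3.51 to 82.1% ± 4.57 at position 2669239 and from 59.9% ± 3.97 to 83.4% ± 5.16 at 2669240 (SD, n = 3, coverage 60 to 224 reads). A CpG in Tery_3181 (TERY_RS15250) was at 18.9% ± 0.918 at 380 µatm at position 4861393, and at 82.0%, 87.9% and 14.1% in the 3 libraries at 750 µatm. Replicate 3 therefore sets its mean difference, which is 42.4 points with it and 66.1 points without it; for position 4861394 on the other strand these are 45.3 and 71.5 points. A CpG in the tRNA gene TERY_RS18570 went the same way, with 45.5%, 36.0% and 17.5% against 18.7% ± 1.25 (SD, n = 3) at position 5974641, where the call ended without replicate 1 at 750 µatm (edgeR adjusted p = 0.0842). The difference was 14.3 points, 22.1 without replicate 3 and 8.08 without replicate 1 at 750 µatm. At 5974642 on the other strand it was 13.6 points, 23.5 without replicate 3, 8.81 without replicate 1 and 8.65 without replicate 2 at 750 µatm. Calls at 3927668, 4632154, 620070 and 6632405 (the first in CWGCWG, the next 2 in CWCCWW and the last in WCGW) each ended or could not be tested in 3 to 5 of the 6 tests that left out 1 library. Without replicate 3 at 750 µatm the difference at 4632154 was 5.49 rather than 9.58 points, and that at 6632405 20.6 rather than 10.4 points, while without replicates 1 and 2 at 750 µatm in turn the latter was 4.18 and 6.50 points. At 3927668 the call ended without replicates 2 and 3 at 380 and 1 and 2 at 750 µatm in turn, and at 620070 without replicates 1 and 3 at 380 and 2 at 750 µatm. By contrast, the calls at 4861393 and 4861394 in Tery_3181 passed in all 6 such tests, although replicate 3 at 750 µatm lay below the 380 µatm mean at both. Passing in all 6 tests therefore does not mean that the replicates agree.

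Summed per gene, 598 of 3253 tested genes were lower and 5 higher (edgeR, adjusted p under 0.05), and the median change of the lower genes was -9.08 points. Of the lower genes, 547 had a tested WCGW cytosine, and 367 stayed lower in all 6 tests that left out 1 library. The 10 with the smallest adjusted p were Tery_3338, Tery_4989, Tery_3145, Tery_2262, Tery_3923, Tery_3468, Tery_0409, Tery_0150, Tery_1787 and Tery_3152, each passing in all 6 such tests. Tery_3338 (TERY_RS15980, 5120787 to 5121026) went from 25.7% ± 2.22 to 5.44% ± 1.72 (SD, n = 3, edgeR adjusted p = 3.4e-05), and Tery_4989 (TERY_RS24065, 7626487 to 7630248), where 35 of 50 tested cytosines were lower, from 48.1% ± 1.72 to 31.1% ± 2.82 (SD, n = 3). The pseudogene Tery_3468 went from 32.8% ± 1.45 to 13.1% ± 2.89 (SD, n = 3). Tery_3923 (TERY_RS18870, 6059266 to 6064635) held 26 tested CpGs outside the words, spaced 123 bases apart in the median, of which 25 were lower, with a mean of 26.3% ± 1.26 at 380 and 9.32% ± 2.19 at 750 µatm (SD, n = 3). The higher genes were dnaJ (44.6% ± 1.66 to 65.1% ± 0.585, SD, n = 3, adjusted p = 0.000111, passing in all 6 such tests), Tery_3181, Tery_1212, Tery_3883 and TERY_RS18570. The call on Tery_3181, Tery_3883 and TERY_RS18570 held only without replicate 3 at 750 µatm, when their differences were 29.7, 11.2 and 10.7 points rather than 17.6, 7.28 and 7.17. Without replicate 1 at 750 µatm they were 11.8, 4.82 and 4.58 points, and without replicate 2 that of Tery_3181 was 11.2 points. The call on Tery_1212 held only without replicate 2 at 750 µatm (adjusted p = 0.0305).

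By fixed list, the nitrogen fixation genes had 3 lower of 7 tested, and also 3 adjusted over the list alone. nifD, for a subunit of the nitrogenase molybdenum-iron protein, fell from 75.5% ± 3.64 to 52.8% ± 8.72 (SD, n = 3), and nifB, for cofactor synthesis, from 79.4% ± 1.67 to 64.5% ± 7.44 (SD, n = 3), each over 2 WCGW cytosines. nifH, for the nitrogenase iron protein, fell from 18.3% ± 2.55 to 7.42% ± 3.22 (SD, n = 3) at 1 cytosine. The nifB call ended without replicate 2 at 380 µatm (edgeR adjusted p = 0.0778), and that of nifH without replicate 1 at 750 µatm (adjusted p = 0.116). No gene passed in photosystem I (2 tested), photosystem II (10 tested) or the phycobilisome (3 tested), also adjusted over the list alone. For example, psbD was at 90.5% ± 0.194 and 90.4% ± 0.392 (SD, n = 3). These 3 lists had few WCGW cytosines, 0 of 9, 2 of 25 and 0 of 5 at 10% or more, against 4 of 15 for nitrogen fixation. Of all tested genes, 37.7% of those with a tested WCGW cytosine were lower, against 2.83% of those without. Lists with few WCGW cytosines thus had less to lose. The single gene tested for iron, feoB, did not pass, nor did the rRNA gene tested, by either adjustment.

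Phosphorus acquisition had 2 lower of 11, and also 2 adjusted over the list alone: phnG of the phosphonate lyase went from 50.8% ± 6.69 to 18.7% ± 5.52 and phnE (Tery_4995), a transport gene, from 66.6% ± 2.09 to 51.4% ± 7.34 (SD, n = 3). Respiration had 2 of 4, both ctaD genes for a cytochrome c oxidase subunit, and 3 adjusted over the list alone. The gene ctaD Tery_0277 went from 66.7% ± 1.42 to 54.5% ± 3.68 (SD, n = 3), and the other ended without replicate 3 at 380 or replicate 2 at 750 µatm. Ribosomal proteins had 3 of 27, and 3 adjusted over the list alone, namely rpsN (41.3% ± 0.832 to 25.2% ± 3.30), rplN (38.2% ± 4.30 to 21.9% ± 3.23, SD, n = 3) and rplE, whose call ended without replicate 1 or replicate 3 at 380 µatm. ATP synthase had 1 of 4 (atpE, 33.9% ± 1.16 to 20.8% ± 3.12, SD, n = 3) and 1 adjusted over the list alone. Gas vesicles had 1 of 5 (gvpN Tery_2334, below the level for testing without replicate 1 at 380 µatm) and 1 adjusted over the list alone, and transposases 0 of 2 and 1 adjusted over the list alone. DNA replication and repair had 7 lower and 1 higher of 22, and 8 adjusted over the list alone. Lower were uvrC (51.8% ± 1.15 to 41.5% ± 2.45, SD, n = 3), recQ, gyrA and recN, which passed with each library left out in turn, and uvrB, recA and dnaK (Tery_1306), which did not. The call for uvrB ended without replicate 2 or 3 at 380 µatm and differed by -4.21 rather than -6.64 points without replicate 3 at 750 µatm, recA without replicate 3 at 380 or 2 at 750 µatm, and dnaK without any one of the 380 µatm libraries. The higher dnaJ and the lower dnaK are chaperones rather than repair proteins. The tRNA genes had 1 lower (TERY_RS00805, 44.8% ± 4.39 to 21.0% ± 5.09, SD, n = 3) and 1 higher (TERY_RS18570) of 14, and 1 adjusted over the list alone.

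Genes with a symbol outside these lists that fell and passed with each library left out in turn included typA, for a ribosome-associated GTPase (38.5% ± 2.57 at 380 µatm, with a difference of -19.5 points), cysE (Tery_4132), for a serine acetyltransferase of cysteine synthesis (31.1% ± 1.41 to 9.79% ± 6.37), and sigC, for a sigma factor of RNA polymerase (74.7% ± 1.12 to 65.1% ± 2.19, SD, n = 3). These 3 were chosen after their values were seen. Of the lists chosen later, aminoacyl-tRNA synthetases, a list that also held hisG and proX genes, had 6 lower of 21 (alaS, aspS, lysS, pheS, gltX and ileS). Central carbon enzymes had 3 of 14, and chaperones and Clp proteases 3 lower and 1 higher of 21. Chlorophyll and heme synthesis had 2 of 12, nitrogen assimilation 2 of 12, ltrA 2 of 5, and cytochrome b6f, cobalamin, cell wall and hormogonium polysaccharide genes 1 each of 5, 14, 14 and 7. Nucleotide synthesis had 0 of 14. Adjusted over the list alone, aminoacyl-tRNA synthetases had 7, ltrA 3 and chlorophyll and heme synthesis 3 calls, and the others the same as above. Members that passed with each library left out in turn were dnaJ, which was higher, and, all lower, alaS, pyk (75.3% ± 0.554 to 66.7% ± 1.51, SD, n = 3), ftsH2, hemB, bchD, petN, cobS, hpsA and ltrA Tery_3634.

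As whole lists, 12 of the 14 fixed lists had a lower mean level at 750 µatm over cytosines at 50% or more, and 0 passed after adjustment, since no exact permutation test of 3 against 3 libraries can go below p = 0.1. The largest difference was that of nitrogen fixation (87.4% ± 0.278 to 79.9% ± 3.17 over 10 cytosines, 4 of them in WCGW, SD, n = 3, exact permutation p = 0.1, adjusted 0.35). Photosystem II (-1.66 points), respiration (-1.18 points) and phosphorus acquisition (-1.81 points) also reached an exact permutation p of 0.1. The 2 lists not lower were the phycobilisome (0.309 points) and the tRNA genes (0.455 points). The other lists had exact permutation p values from 0.2 to 0.8: DNA replication and repair differed by -1.75 points, photosystem I by -2.74, iron by -2.57, ATP synthase by -0.807, transposases by -0.790, gas vesicles by -0.616, ribosomal proteins by -0.326 and rRNA genes by -0.253 points. Among the lists chosen later, 0 of 11 passed, and differences ran from -23.7 points for ltrA, which rests on 1 cytosine, to -0.591 points for central carbon enzymes.

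The third question was how far the IMS101 methylome is shared with other Trichodesmium. The isolate IMSB shared nearly all of it, and VI-1 and the natural populations shared fewer than 46% of sites, least at WCGW. Of the 12427 methylated cytosines, 12418 (99.9%) were listed for IMSB, 5358 (43.1%) for VI-1, 5690 (45.8%) for St-06 and 4965 (40.0%) for St-08. Since the methylomes sit on the same words, these counts were set against lists drawn at random within each word, which give 6467, 3458, 3968 and 3403. This contrast was chosen after the data were seen. Whether the lists share places by depth of reads, by genome sequence or by the A and T bases that a word leaves open was not tested. A cytosine that is not listed may be unmethylated, absent from that genome or not covered, since the lists hold only cytosines at 20% or more with at least 5 reads. Of the listed cytosines, 40.7% in VI-1, 30.5% in St-06 and 37.1% in St-08 rested on 1 methylated read of 5, against 0.380% in IMSB. When a level of 50% and 10 reads were asked of the listed sites, the shares were 97.2%, 20.9%, 25.5% and 22.8%.

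The words differed in how often they were shared. CGWWCG sites of IMS101 were listed for VI-1, St-06 and St-08 at 60.5%, 67.7% and 60.8%, against 41.5%, 52.8% and 40.6% of the CGWWCG cytosines not methylated in IMS101 (Fisher's exact test, odds ratios 2.16, 1.87 and 2.27). CWGCWG sites were listed at 52.1%, 56.0% and 48.8%, against 2.48%, 2.97% and 2.82% (odds ratios 42.8, 41.6 and 32.9), and WCGW sites at 22.8%, 18.6% and 13.7%, against 0.639%, 1.14% and 0.877% (odds ratios 45.8, 19.8 and 18.0). IMSB listed all 1943 CWGCWG sites and 0% of the other CWGCWG cytosines. Where a word pools sequences of which only some are methylated, such odds ratios do not measure sharing of single places alone. GCSGC sites were listed at 41.4%, 45.8% and 40.5%, and since 3731 of 3733 were methylated in IMS101, no contrast within that word was possible. At a level of 50% and 10 reads, WCGW dropped to 0.842%, 2.53% and 0.903%, while IMSB kept 90.8%. Levels of shared WCGW sites with at least 10 reads were 31.2% in VI-1, 45.7% in St-06 and 35.8% in St-08, against 81.5%, 78.8% and 79.2% for the same sites in IMS101. In IMSB they were 77.4% against 79.6%.

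**Figure D4:**
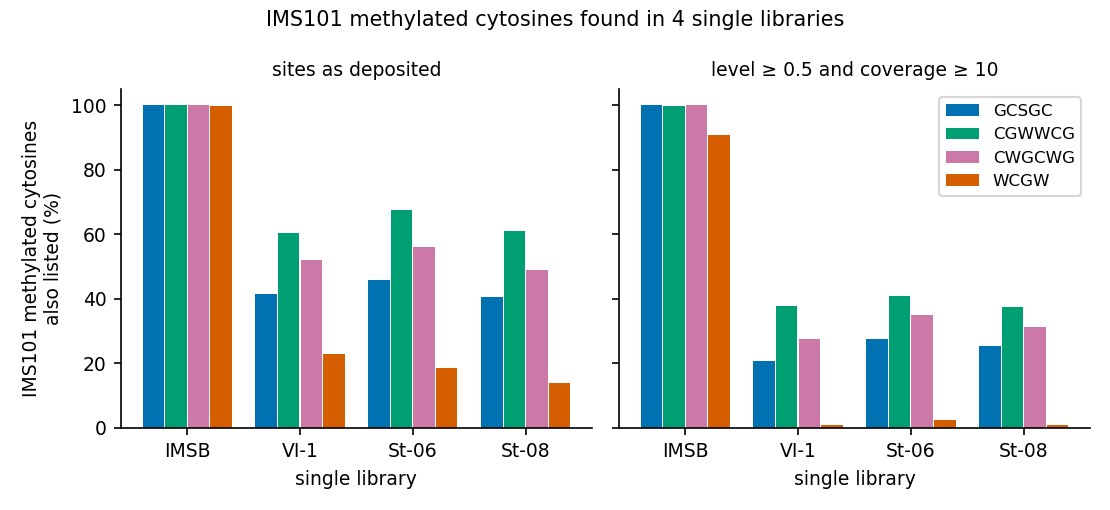
Share of the IMS101 methylated cytosines of each sequence word that is also listed for each single library (vertical axis, %), for sites as deposited (left) and for listed sites with a level of at least 50% and at least 10 reads (right). IMSB holds 90.8% or more in each word, and WCGW is the lowest of the 4 words in VI-1, St-06 and St-08.

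Methylated in IMS101 and listed for all of IMSB, VI-1, St-06 and St-08 were 3302 cytosines (26.6% of the IMS101 set), 5.37 times the 615 that lists drawn at random within each word would give. They included 1568 CGWWCG, 975 GCSGC, 649 CWGCWG and 109 WCGW cytosines, 46.8%, 26.1%, 33.4% and 3.28% of the IMS101 sites of each word. Genes held 3026 (91.6%) of them, and 1289 genes had at least 1. The most were in Tery_0826 (1308378 to 1312364), with 23 of its 38, followed by Tery_3677 and Tery_1546 (13 each), Tery_0904 (12 of 12), Tery_3964 and Tery_1841 (11 each), Tery_2763 and Tery_3459 (10 each), and groL (Tery_0270), for a chaperonin, with 9 of 16. Tery_2501, Tery_4713, Tery_1840, Tery_2158, Tery_1188 and Tery_3869 had 8 each, and in Tery_4713 and Tery_1840 these were all of the sites in the gene. At a level of 50% and 10 reads the count was 2103, a drop of over 1.5 times, and 21.2 times the 99.0 from lists drawn within each word. Both ratios take the lists as independent within a word, so lists that hold the same covered places raise them too. They also take all places of a word as alike, though A and T were not told apart. If only some of the sequences in a word are methylated, the ratios rise as well. Of GCSGC sites, VI-1, St-06 and St-08 listed 41.4%, 45.8% and 40.5%, and 26.1% were common to all. That is more than independent lists would give, in a word where 3731 of 3733 places were methylated in IMS101. The ratios therefore do not measure shared methylation alone.

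In 4 of the 14 fixed lists a larger part of the methylated cytosines was common to all 5 methylomes than in other genes when both strands were counted, and in 0 when each place was counted once. The Fisher's exact tests gave adjusted p values from 0.0796 on the plus strand alone and from 0.321 on the minus strand alone, with 1 list below an unadjusted 0.05 on the plus and 0 on the minus strand. Ribosomal protein genes had 23 of 42 (54.8%, odds ratio 2.83, Fisher's exact test, adjusted p = 0.0146, and 0.0796 and 0.321 on the plus and the minus strand alone), with 4 in rplT and 2 in rplY. Photosystem II had 12 of 20 (odds ratio 3.49, adjusted p = 0.0287, and 0.312 and 0.321), with 4 in psbD and 2 in psbP, and this call also ended at a level of 50% and 10 reads (7 of 20, adjusted p = 0.438). Photosystem I and iron each had 4 of 4 (adjusted p = 0.0287, and 0.312 and 0.321 each), which are 2 places read on both strands in a single gene each, psaB and feoB. The other 10 lists had adjusted p values from 0.204 to 1. ATP synthase had 7 of 13 (3 in atpA, 2 in atpC), DNA replication and repair 37 of 112 (6 each in uvrB and recJ) and tRNA genes 11 of 27 (3 in TERY_RS20035, 2 in TERY_RS17430). Phosphorus acquisition had 11 of 35 (2 each in phnH and phnE Tery_4996), nitrogen fixation 2 of 10, both in nifK, and respiration 2 of 12, both in ndhC. Phycobilisome, transposase, gas vesicle and rRNA genes had 0 of 4, 0 of 4, 0 of 2 and 0 of 2.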

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

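The tests on the lower sites and genes and on CWCCWW were chosen after the results they bear on were seen, and the test on GCWGC was set before.

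The cytosines and genes lower at 750 µatm may reflect the growth conditions, which were not tested apart from anything else that differed between the groups of cultures, such as the time in culture or the day of harvest, for which the labels give no batch. If unconverted cytosines were spread evenly over sequences, more of them at 380 µatm could raise a level there by no more than the share of methylated reads outside the words. That share was at most 0.382% in a library, 0.0453 times the 8.45 points by which WCGW fell. It sets no limit for unconverted cytosines that gather at WCGW. Words near full level have no room to show a raised level. They have room to fall if more methylated cytosines were converted at 750 µatm, but the larger share of its level lost by GCSGC or CWGCWG was 0.0289 times that lost by WCGW. CGWWCG, also at intermediate levels, lost 6.56% of its level against 13.6% for WCGW (0.481 times), with a lower mean at 85.6% of its sites. Most of this CGWWCG loss rested on replicate 3 at 750 µatm, at 45.6%. Replicates 1 and 2 at 750 µatm were at 54.3% and 51.9%, against 52.7%, 53.9% and 55.9% in the 380 µatm libraries. Why replicate 3 was lower there was not tested. The lower depth of replicate 3 at 750 µatm was not needed either, since the WCGW difference without that library was 1.04 times that with it. The 6 libraries allow 10 splits, so the share of splits as extreme cannot be below 0.1: the real split called 2367 sites and 603 genes and the highest of the others 0 of each, so 1 split of 10 gave as many sites, and 1 as many genes. Whether CO2 or another difference between the cultures lowered the level at these CpGs stays open.

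A signal outside the 4 words lay at 2875 of 30427 CWCCWW cytosines, whose mean level over the 6 libraries was at least 5%, at 10.3% ± 0.106 at 380 and 10.8% ± 0.385 at 750 µatm (SD, n = 3), while 55 of 1830430 other CHH cytosines reached 5%. The comparison of 750 with 380 µatm tested 1909 CWCCWW cytosines, with 3 lower and 8 higher calls. Levels fell into 2 groups, with 27534 cytosines under 2% and 1 between 4 and 6%. Incomplete conversion of a library is unlikely as the whole cause, since replicate 3 at 750 µatm was 1.08 times the mean of the other 5 libraries here while its other CHH cytosines were 1.82 times theirs. A property of C-rich words in general is unlikely as well: the word with the highest share of such cytosines up to position 3875053 was CWCCWW, and beyond that position, which had no part in the choice, the highest share in a word 1 base away was 0.00109 times that of CWCCWW. These tests were first set over all CWCCWW cytosines, most of them at background, where the ratios of 1.27 and 0.329 decided nothing, and were then restricted to the group at 5% or more, a limit chosen on the whole chromosome; a partly protected or partly methylated base is a candidate explanation that was not tested.

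GCWGC differs from the IMS101 word GCSGC at its middle base and was listed (level of at least 50%, 10 reads) at 3.42% of the places not methylated in IMS101 in VI-1, 4.05% in St-06 and 3.92% in St-08, against 0 of 18390 in IMSB. Sequence differences from the IMS101 genome could produce this, with a place that reads GCSGC in those cells. Other words 1 base away from GCSGC reached at most 0.685 times the rate of GCWGC, in VI-1, where GCSGG was listed at 2.34%; in St-08 the highest was 0.635 times (GCSGG, 2.49%) and in St-06 0.187 times, so the libraries differed in how far other words came near that rate. GCWGC also overlaps CWGCWG: 581 GCWGC cytosines were methylated in IMS101, and CWGCWG cytosines were not taken out of the places searched. At this level and depth VI-1, St-06 and St-08 listed 737, 907 and 833 CWGCWG cytosines, of which 535, 682 and 607 were methylated in IMS101, so others may count here. The sequence of those genomes was not used here, so a broader recognition of GCSGC, methylation of CWGCWG and a changed sequence cannot be told apart.

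In the library 21-75, which no comparison used, 966 cytosines in CHH had a level of at least 50% and at least 10 reads, against 0 in IMSB, 429 in VI-1, 334 in St-06 and 442 in St-08. Their mean level was 58.5% and 96.7% of them lay within 20 bases of another on the same strand, against at most 9.88% in the others.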

How the results depend on the processing

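Of 94 values under alternatives, 65 kept their size or their side of the threshold, 29 moved and 0 reversed. With a minimum level of 0.2 or 0.8, CpG made up 75.1% or 55.8% of methylated cytosines, and 4 lists passed for density under each; at 0.2 these added nitrogen fixation (adjusted p = 0.0352) and photosystem II (0.0352) below other genes, at 0.8 transposases and phosphorus acquisition (0.0488 each) above them. The mean level differed by -3.91 points at a level of at least 0.2, -0.631 at 0.8 and -4.10 over WCGW alone. Sites called fell to 447 at a level of at least 0.5 and 292 without WCGW. There 11702 and 13384 cytosines were tested rather than 18410, and only 542 and 381 of the 2367 main calls were among them. Genes called were 204 at 0.5, 313 without a level minimum, 373 with limma and 59 without WCGW. The mean share of IMS101 sites listed fell to 35.5% at a listed level of 0.8, and sites common to all methylomes to 2103 (level 0.5, 10 reads), 1204 (level 0.8) and 2153 (IMS101 level 0.8), stricter lists by construction. Beyond that the cause was not tested. Leaving out each library in turn gave 1755 to 2659 sites, 408 to 709 genes, mean differences from -2.80 to -1.50 points and 12283 to 12529 methylated cytosines. Pooled Fisher tests, which ignore replicate spread, called 3060 sites. Thinned to the shallowest library, chosen after seeing the data, reads gave 1725 sites and 496 genes. On the plus or the minus strand alone, also chosen after seeing the data, 1 list passed for density (tRNA genes) rather than 2, and 0 rather than 4 for cytosines common to all methylomes; each place counts once there, by construction.

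With the replicate number as a block, 2090 sites and 487 genes were called and the exact sign-flip p for the mean level was 0.25. No sign was found that the numbers pair the samples, though such a pairing is not excluded. Correlations of deviations between libraries of the same number were -0.147, 0.0235 and -0.103. Libraries 1 and 3 of each group correlated best with another number, while those of number 2 did so with each other at 0.0235 alone.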

Other observations

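The single lists also hold cytosines outside the 4 words. At a level of at least 50% and 10 reads they made up 29.9% of the sites of VI-1, 24.6% of St-06 and 31.2% of St-08, against 0.453% of IMSB. C, A or T, then G held 25.7%, 27.9% and 28.1% of these sites in the 3 libraries, against 15.5% in IMSB, and CpG held 55.9%, 56.5% and 51.8%, against 69.6%. In the isolate 21-75, CpG held 69.5%, C, A or T, then G held 12.3% and CCG held 11.3%. Over the lists as deposited, CHH held 45.7% in VI-1, 33.2% in St-06, 35.6% in St-08 and 41.4% in 21-75, against 0.482% in IMSB. CpG held 32.3%, 41.4%, 37.7% and 44.0% of these 4 lists, against 74.7% in IMSB. CGWWCG levels at shared sites with at least 10 reads were 76.8% in IMSB against 72.2% in IMS101, and the levels of the 3345 sites correlated across sites with r = 0.887; across the 1373 sites shared with VI-1 r was 0.273. Sites are not independent replicates.

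Some WCGW cytosines split the 750 µatm libraries. At 35 of 5026 tested cytosines, replicates 1 and 2 moved by at least 30 points from the 380 µatm mean while replicate 3 stayed within 10 points of it, as in Tery_3181. The 2 other combinations of libraries gave 0 such cytosines, and at 9 cytosines all 3 moved by at least 30 points. At CGWWCG replicate 3 stood apart in the other sense, as the lowest of the 6 libraries at 72.5% of 5548 tested cytosines. If the libraries were alike in level and depth, 16.7% would be expected. Its lower depth, 83.4 reads per cytosine against 179 to 209, would raise that share by an amount that was not tested.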
